A study of Caenorhabditis elegans with 4 samples.

How the data were processed

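The series is a chromatin immunoprecipitation sequencing (ChIP-seq) study of CEH-30, a homeodomain transcription factor of Caenorhabditis elegans. Per the labels' protocols, worms of strain OP120, which carry a ceh-30 transgene with a GFP and FLAG tag, were grown at 20 °C, crosslinked at the late embryo stage with 2% formaldehyde and quenched with 100 mM Tris. Chromatin was sheared by sonication and precipitated with an affinity-purified goat antibody against GFP. The labels describe 4 samples, which are 2 of immunoprecipitated DNA and 2 of input DNA, with replicate numbers shared between both kinds. The labels name separate extractions for the replicates.

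The data used here were 1 list of called regions for the whole series, with no values per sample. Per the file headers, the authors' coordinates refer to WormBase release WS180, and the source column of the list names PeakSeq, a caller that scores regions of immunoprecipitated DNA against input DNA. Each region had a start, an end and a q-value (a p-value adjusted for multiple tests), deposited by the authors in a list named as combined. The q-value was written in 2 fields, which differed in 0 of the 6672 regions. A q-value of 0.01 or more was found in 0 regions. The aligner, the PeakSeq version, the filters and the way the replicates were combined are not given in the sources used here. No read counts came with the list, so the depth behind a region is unknown, no error between replicates could be computed, and a q-value reflects depth as well as enrichment. No gap between neighbouring regions was shorter than 200 bp. The list holds regions above a significance limit only, so a stretch with no region is a stretch with no call.

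From the list, the width and midpoint of every region were computed, and the −log10 of the deposited q-value was used as its strength. Strength is used to rank, describe and compare regions within this list only, and the tests of strength apply to this list alone. The span of a chromosome was taken as the end of its last region. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The share of regions on X was tested with a two-sided circular-shift permutation test, in which all midpoints were moved together by 1 random offset along the 6 chromosomes laid end to end, 10000 times. Each chromosome span was also cut into 3 equal parts, a left, a central and a right one, and the share of regions in the central part was tested in the same way with separate offsets within each chromosome. Such shifts keep the local crowding of the regions. They also keep broader differences in density, which for the end-to-end shifts include those between chromosomes. The range that a share is set against therefore holds these differences too. Clustering was tested one-sided as the share of midpoints with another midpoint within 5 kb, against 1000 uniform placements of as many regions. Strength on X and on the autosomes was compared by a two-sided permutation test of the difference in medians, with 100000 resamples, and strength was correlated with width with 100000 permutations. Regions are not independent replicates, and every p-value here describes the arrangement of this list, not the spread between cultures.

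The design fixed before the data were examined also chose the regions to name: the 10 with the smallest q-values, the 5 widest, the strongest of each chromosome, and the 5 most crowded 50 kb windows on a fixed grid. Alternatives fixed at that time were the better 50% and the best 10% of the q-values, a q-value limit 10 times stricter, regions within 500 or 2000 bp joined, other distances and zones, covered bases in place of region numbers, and, for the share on X, leaving out each autosome. Tests of each chromosome and of each of its 3 parts, shifts of the strengths and of the widths along the ordered regions, and lists without regions under 20 bp or without the crowded windows were chosen after seeing the data, as was leaving out each autosome for the central part and for the strength on X. A further 6 planned results, on gene starts, annotation classes, gene lists and sequence motifs, needed a genome or annotation of release WS180. The gene table at hand was of assembly WBcel235, coordinates were not converted between releases, and these results were not run. Regions are therefore given by position, and their genes, exons and introns were not analysed here.

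The tests were first tested on simulated data with the same 6672 regions and chromosome spans. With regions in clusters of 4 and no effect, the test of the share on X called 8 of 100 simulated lists and the test of the central part called 4 of 100. With a 1.3-fold higher density on X, the test of X called 84 of 100 lists. With a 1.3-fold higher density in the central part, the test of the autosomal central part called 100 of 100 lists. Apart from the clusters and the set difference, these lists were uniform. They lacked the other differences in density and the long gaps of the real list. The numbers called are therefore not the power or error rate of the tests on the real list. The clustering test called 0 of 20 uniform lists and 20 of 20 clustered ones. The uniform lists were drawn as its placements are, and the clusters were made close together. Both of these results were thus largely set in advance. All simulated lists were tested with fewer shifts, placements and resamples than the real list. The comparison of strengths called 2 of 40 unchanged lists and 40 of 40 lists in which X was raised by 0.5. In these lists the strengths were shuffled over the regions, which removes any likeness between neighbours. The number of unchanged lists called was thus fixed by the shuffling. It does not show how often the comparison calls a list whose neighbouring strengths are alike.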

Results

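CEH-30 is a homeodomain protein of the Bar family, known for its role in the survival of the male-specific CEM sensory neurons. The series was made to map where the GFP-tagged protein was bound to the genome of late embryos labelled as hermaphrodite. DNA from 2 anti-GFP immunoprecipitations was set against DNA from 2 input samples, and the authors combined them into 1 list of regions. The question addressed is which parts of the genome the antibody recovered above input. The labels describe no sample without the tag. Binding of CEH-30::GFP therefore cannot be told apart from other recovery by the antibody. Values per replicate were not part of the list, so no value below has an error between replicates. The depth behind each region is unknown.

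CEH-30::GFP regions were found on all 6 nuclear chromosomes, and they were mostly short. The list held 6672 regions, or 66.7 per Mb of the 100.1 Mb spanned, and they covered 1.48 Mb, which is 1.48% of that span. The median width was 174 bp, with quartiles of 70 and 291 bp. The median q-value was 0.000341, with quartiles of 2.76e-06 and 0.00255. The corresponding strength, the −log10 of the q-value, had a median of 3.47 and quartiles of 2.59 and 5.56. At the other end, 64 regions were wider than 1 kb and together held 11.2% of all covered bases.

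The strongest region lay on chromosome I at 5371410 to 5380164 (coordinates are 1-based, WormBase WS180). It was 8755 bp wide and had a q-value of 1.28e-251. The strongest region of chromosome II, at 14404776 to 14408337, followed with 4.77e-211, and that of V, at 1803796 to 1806743, had a q-value of 6.09e-186. On III the strongest region was at 9050147 to 9054219, with 1e-169. The strongest region of IV was 1621 bp wide, at 1623802 to 1625422, and had a q-value of 7.87e-127. The strongest X region lay close to it in rank, at 16929367 to 16931967, with 6.73e-126. Chromosome I held 2 more of the 10 strongest regions, at 13499559 to 13501237 and at 13600246 to 13602418, with q-values of 4.88e-129 and 3.79e-166. The remaining 2 of the 10 were narrower than 1 kb. They lay on V at 9088611 to 9089267, with a q-value of 6.39e-114, and on II at 2221228 to 2222210, with a q-value of 3.41e-108.

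The 3 widest regions were not among the 100 strongest, but all of them lay in the best 10% of the q-values. A region of 14112 bp on V, at 10057086 to 10071197, ranked 118 by q-value (5.78e-20). On IV, a region of 14044 bp at 8471404 to 8485447 ranked 594 (2.05e-10), and its neighbour of 10753 bp at 8485661 to 8496413 ranked 405 (1.78e-12). These neighbours on IV covered 99.15% of a stretch of 25010 bp. On V, a further wide region of 5813 bp at 10080719 to 10086531 ranked 11 (7.46e-93), and it lay in a stretch of 17.9 kb, from 10074127 to 10091990, of which 5 regions covered 83.3%.

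**Figure D1:**
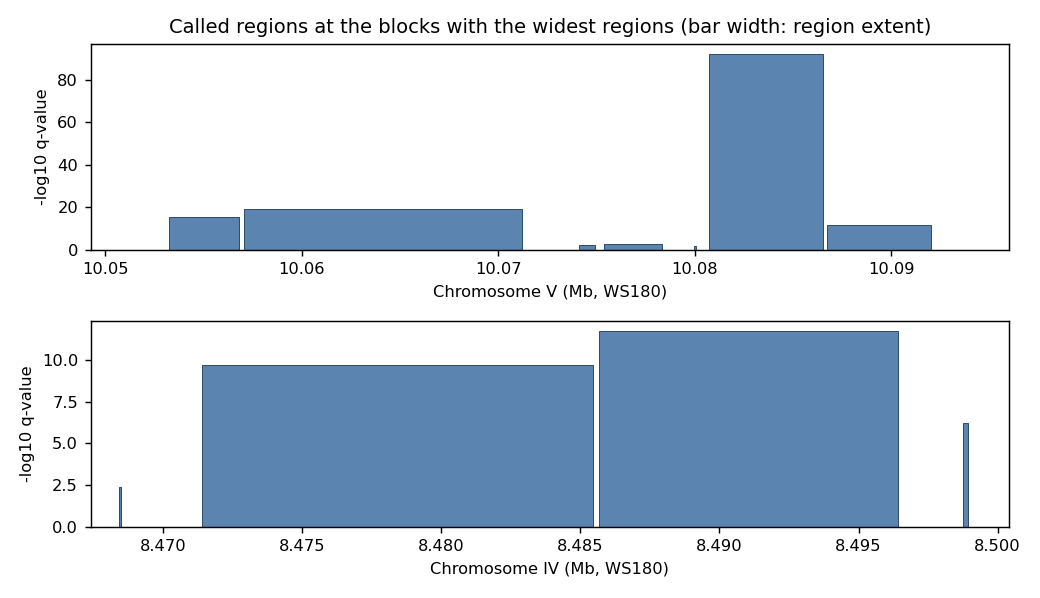
Called regions around the widest ones on chromosomes V (top) and IV (bottom). The x axis is the position in Mb (WS180), each bar spans a region from start to end, and its height is the −log10 of the authors' q-value. The y scales of the panels differ. On V, the bar of 14112 bp (strength 19.24) is low beside the bar of 5813 bp, whose strength is 92.1. On IV, the bars of 14044 and 10753 bp have strengths of 9.69 and 11.75.

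Wider regions had smaller q-values across the list. Strength and width were correlated across the 6672 regions with a Spearman rho of 0.62 (permutation p = 1e-05) and a Pearson r of 0.50 (permutation p = 1e-05), each p being the smallest that 100000 permutations can give. With 2 coefficients tested, the Benjamini-Hochberg adjusted values are the same. The same caller set width and q-value from the same reads, so they are not independent measures. The p-values therefore cannot separate a property of binding from one of the calling. Regions of 400 to 1000 bp had a median strength of 8.07, and the 64 regions above 1 kb had a median of 20.6. Regions of 100 to 199 bp had a median of 3.14. The 786 regions under 20 bp, of which 111 were 1 bp wide, had a median of 2.59 and none had a q-value below 5.53e-06. The correlation was also present within X, with a rho of 0.65, and within the autosomes, with a rho of 0.63.

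**Figure D2:**
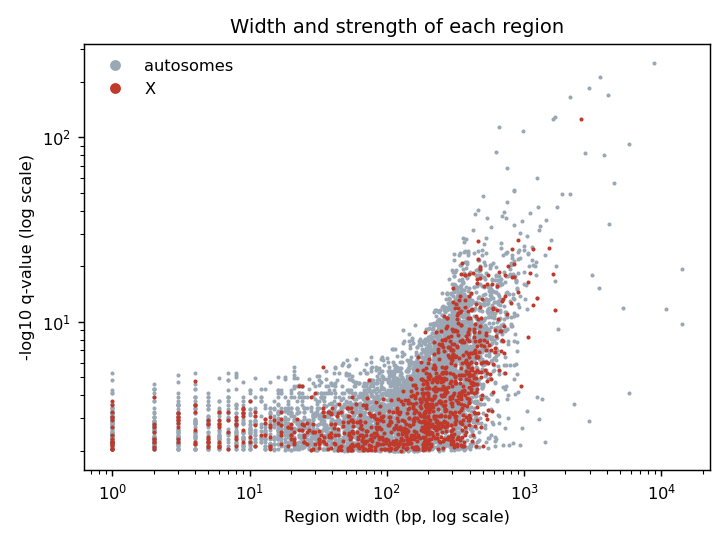
Width (x axis, bp, log scale) and strength (y axis, −log10 q-value, log scale) of each of the 6672 regions, with X in red and the autosomes in grey. Strength rises with width (Spearman rho 0.62), and the 3 widest regions lie far below the strongest ones.

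The density of regions was highest on III and I and lowest on V, and every share lay within the range that shifts of the whole pattern gave. Those shifts carry the differences between chromosomes along with them. The test therefore cannot show that the chromosomes are alike in density. Chromosome III held 1163 regions (84.4 per Mb) and I held 1232 (82.3 per Mb). II held 1082 regions (70.9 per Mb), IV 1033 (59.2 per Mb) and V 1080 (51.8 per Mb). The share on III was 17.4% of all regions, and 95% of the shifts gave between 10.2% and 17.8%. In this test of all 6 chromosomes, chosen after seeing the data, III had the smallest p (circular-shift permutation test, two-sided, p = 0.0377, Benjamini-Hochberg adjusted p = 0.226).

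X held 1082 regions, or 61.1 per Mb, against 67.9 per Mb on the 5 autosomes. Its share of the regions was 16.22% (95% Wilson interval 15.4% to 17.1%, counting error only), and it makes up 17.7% of the span. The shortfall was within what shifts of the pattern gave, 13.2% to 21.8% (circular-shift permutation test, two-sided, p = 0.79). This test thus did not call a difference in density of X. Its range holds the density differences between chromosomes, since the shifts carry them along. The result therefore does not show that X is as dense as the autosomes.

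The median region on X was weaker and wider than the median autosomal one. The median strength was 3.09 on X (quartiles 2.44 and 4.86, 1082 regions) and 3.54 on the autosomes (quartiles 2.63 and 5.68, 5590 regions). The difference, X minus autosomes, was −0.45 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). In the widest quartile of regions, from 292 bp up, the medians were 5.96 on X and 7.59 on the autosomes. In the narrowest quartile, up to 70 bp, they were 2.51 and 2.71. The median width was 197 bp on X and 169 bp on the autosomes, a difference of 28 bp (two-sided permutation test by shifts of the widths along the regions, chosen after seeing the data and unadjusted, p = 0.0215). The difference in strength no longer passed the threshold when the strengths were shifted along the ordered regions, which keeps neighbouring values together (two-sided permutation test, p = 0.0985), although −0.449 lay just outside the middle 95% of these shifts, −0.447 to 0.576, which were skewed. IV and V had medians of 3.24 and 3.26, close to that of X, while I and III had 3.74 and 3.94.

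The best 10% of the q-values made up 13.5% of the regions of I, 11.8% of those of III and 11.5% of those of II. On V the share was 7.78%, on X 7.58% and on IV 7.26%. For I, shifts of the strengths along the regions gave 6.98% to 13.7% (two-sided shift permutation test, p = 0.055, Benjamini-Hochberg adjusted over 6 chromosomes p = 0.33), and no other chromosome had a smaller p.

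**Figure D3:**
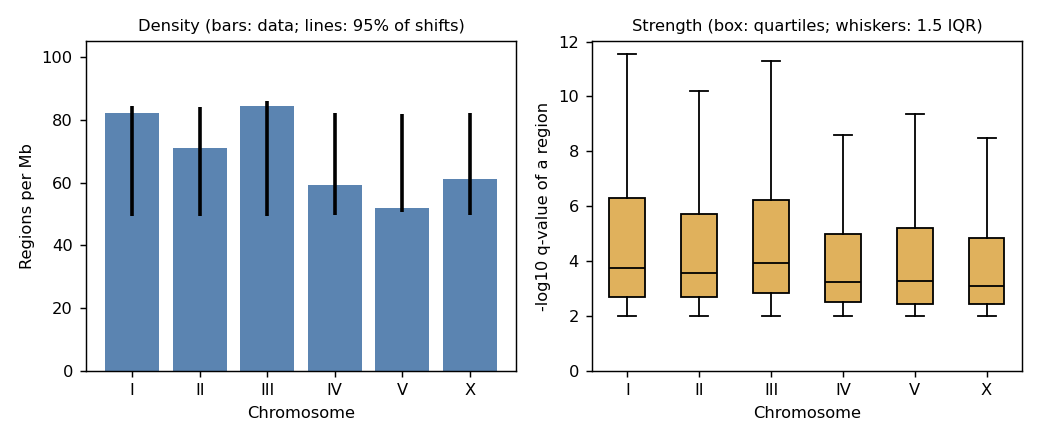
Left, regions per Mb on each chromosome (bars), with the range of 95% of circular shifts (black lines); every bar ends within its line. Right, strength of the regions of each chromosome (y axis, −log10 q-value; box, quartiles and median; whiskers, 1.5 times the interquartile range, values beyond not drawn); the median is lowest on X (3.09) and highest on III (3.94).

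Along the chromosomes, regions lay in all 3 equal parts of each span. The worm's autosomes have gene-dense centres between arms that are richer in repeats. Of 3 equal parts of each span, the central one held 34.8% of the autosomal regions, and shifts within chromosomes gave 30.3% to 36.1% (circular-shift permutation test, two-sided, p = 0.349). For the central 50% of each autosomal span, the share was 53.4%, above the 47.0% to 53.0% that shifts gave (p = 0.0232, permutation test). That split was 1 of 12 alternatives, and its p-value is unadjusted. Neither split uses the actual borders between arms and centres. On X, the 3 parts held 361, 361 and 360 regions from left to right. On II, the left part held 24.1% of the regions and the central part 39.3%. On IV, the left part held 37.7%. None of the 18 parts passed the threshold after adjustment over all of them, and the smallest p was that of the left part of IV (permutation p = 0.0166, adjusted p = 0.299).

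At short range the regions were clustered. Another region lay within 5 kb of 60.1% of the regions, against a mean of 48.7% and a highest value of 50.9% in 1000 uniform placements (permutation test, one-sided, p = 0.001, the smallest these placements can give). Within 2 kb the share was 35.9% against a mean of 23.4% (p = 0.001, permutation test). Within 20 kb it was 92.6%, below the placements' mean of 93.0%. The list alone does not show whether close regions are separate sites or blocks split by the caller. With regions within 2000 bp joined, in the list and the placements alike, the share within 5 kb was 32.7% against a mean of 29.3%. That comparison was added after seeing the data.

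Clustering was most pronounced in a few 50 kb windows, where the mean was 3.33 regions per window over 2005 windows. The windows at 11.10 to 11.15 Mb on I and at 17.65 to 17.70 Mb on V each held 27 regions. A window at 6.80 to 6.85 Mb on II held 20, and those at 17.50 to 17.55 Mb on V and 13.50 to 13.55 Mb on I held 16 and 15. No window had more than 16 regions in 1000 uniform placements. The crowded windows differed in strength. The window at 13.50 Mb on I held one of the 10 strongest regions at its left edge, with a strength of 128.3 within it, and that at 11.10 Mb on I reached 49.1. On II the highest strength in the window was 9.39. On V none of the 27 regions exceeded 4.73 and none of the 16 exceeded 5.01.

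**Figure D4:**
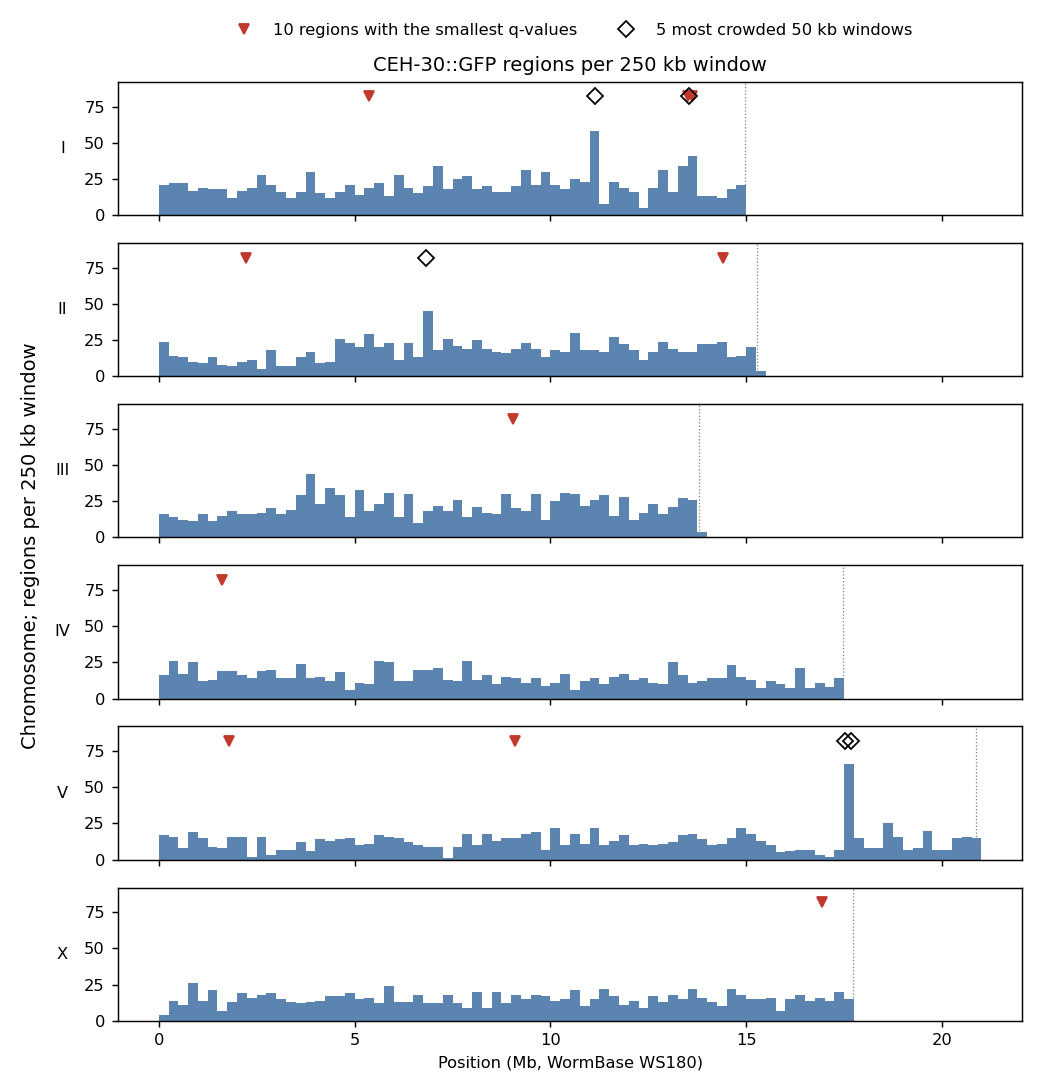
Number of regions per 250 kb window (y axis) along each chromosome (x axis, Mb, WS180; dotted lines mark the end of the last region). Red triangles mark the 10 regions with the smallest q-values and open diamonds the 5 most crowded 50 kb windows; the fullest 250 kb window, at 17.50 to 17.75 Mb on V, held 66 regions against a median of 16.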

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

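The share of regions on X stayed below its expected share and short of the threshold under all 12 alternatives, from 12.3% to 19.9% (the higher values with an autosome left out), and both correlations of strength with width kept their sign and call under their 3 alternatives. The better 50% of the q-values held 3336 regions, the best 10% 668 and the limit 10 times stricter 4083; the best 10% covered 422.3 kb with a median width of 404.5 bp. Joining regions within 2000 bp raised the covered length from 1481.3 to 2915.8 kb, since it adds the gaps. The central part of the autosomes held 31.6% of their best 10% of regions, below expectation where the full list was above it, and the central 50% of the span, with 53.4%, passed the threshold; the cause was not tested. On X, whose share in the central part equals its expectation within 0.1 percentage points, the side changed without passing the threshold: 31.7% in the better 50%, 24.4% in the best 10%, 32.9% and 32.4% with regions joined within 500 and 2000 bp, and 32.4% without regions under 20 bp. Clustering within 5 kb fell to 32.7% after joining within 2000 bp, below the 40.04% of unjoined placements, because joining removes the closest neighbours; when 200 placements were joined in the same way, an alternative added after seeing the data, their mean was 29.3% and 32.7% was again above all of them (permutation p = 0.005, the smallest they can give). Within 20 kb, 92.6% lay below the mean of the placements. Without the 5 most crowded windows, 59.5% of regions were clustered within 5 kb. The lower strength on X kept its sign in all 10 alternatives, from −0.83 to −0.16 (the latter on a log2 scale), but lost its call when strengths were shifted along the regions (−0.449, two-sided p = 0.0985, just outside the middle 95% of the skewed shifts, −0.447 to 0.576) and when the X label was shifted within width quartiles (−0.83, p = 0.121, permutation tests); both set X against runs of as many neighbouring regions. No paired analysis was possible because the list holds 1 value per region over both replicates; leaving out a replicate could not be run for the same reason. Alternatives for gene starts, gene lists and motifs were not run. Depth is unknown and limits every statement on absent or weak regions.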

Other observations

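Tests in this part were chosen after the values were seen, except the joining of neighbours among the strongest regions. Long stretches held no region, and V had more of them than any other chromosome. Of 49 gaps above 100 kb, 22 lay on V, 12 on IV, 8 on X, 5 on II, 2 on III and 0 on I; the highest number in 1000 uniform placements over all chromosomes was 19 (permutation p = 0.001, the smallest these can give). The longest, of 324.2 kb, lay on V at 17122351 to 17446587, next to the crowded windows at 17.50 and 17.65 Mb. The next were 291.8 kb on V at 2278881 to 2570668, 230.6 kb on II at 1819397 to 2050026, 228.5 kb on IV at 4810590 to 5039051 and 228.2 kb on V at 7237438 to 7465601. The sequence under these gaps was not analysed here. Uniform placements lack the short-range clustering of the regions, and clustered regions leave longer gaps between them. The p-value for the number of gaps thus restates that clustering at least in part. The number on V was not tested on its own. V also had the longest span (20.86 Mb) and the lowest density (51.8 per Mb).

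The strongest regions sat near each other. Of the 100 with the smallest q-values, 40 had another of them within 50 kb. Permuting the strengths over the fixed positions gave a mean of 11.2 and at most 29 (one-sided p = 0.0001, permutation test). That p is the smallest that 10000 permutations can give. Crowding of all regions regardless of strength thus does not account for the number. The permutations break any link between strength and crowding, so crowding that goes with strength was not excluded. If the caller had split single enriched blocks, joining regions within 2000 bp should have brought the number into the permuted range. The number was 28, above 18, the upper end of the middle 95% of permutations (p = 0.0003, permutation test). It was not above the highest permuted value of 30. Splitting at gaps up to 2000 bp may thus account for part of the excess and not for all of it. Splitting across longer gaps was not tested, since this joining does not reach them. Chromosome I held 33 of the 100, with 8 between 13499559 and 13756741; with I left out, 36 of the then 100 strongest had such a neighbour (p = 0.0001, permutation test). No biological explanation was tested.

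The crowded windows differed in strength. In the V window at 17.65 Mb the highest strength was 4.73, and 0.55% of 10000 runs of as many neighbouring regions were as weak or weaker; at 17.50 Mb on V it was 5.01 and 1.04%. For the window on II, with 9.39, the share was 16.6%, and for those on I at 11.10 and 13.50 Mb it was 93.4% and 98.6%. For both V windows together it was 0.01%, but their low strengths prompted this test, so it restates them and cannot tell whether a raised local baseline near the threshold lies behind them. Joining regions within 500 bp left 22 and 11 regions in the V windows and joining within 2000 bp left 8 and 5, so single enriched blocks split by the caller cannot be told apart from separate regions. No read counts were at hand to decide either, and no biological explanation was tested.

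Regions under 20 bp made up 11.8% of the list. If they were edges cut off from wider regions, most should have had another region within 1 kb; 21.6% had one (95% Wilson interval 18.9% to 24.6%, counting error only), against 24.1% of the other regions, so 78.4% are not such edges within that distance. The difference in median strength, regions under 20 bp minus the others, was −1.13, which follows from the correlation of strength with width and leaves open whether these are sites whose enrichment just reaches the threshold. No biological explanation was tested.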
